A study of Bos taurus with 16 samples.

How the data were processed

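RNA was measured in 16 libraries, 9 labelled control and 7 labelled treatment. Per the labels' protocols, granulosa cells were pelleted from the aspirate of the dominant follicle and washed, and total RNA with an integrity number of at least 7 was used. From 200 ng of RNA, poly(A) RNA was isolated and libraries were made with a kit that does not mark strand and 12 cycles of amplification. Reads of overlapping and antisense genes therefore cannot be told apart. Per the submitters' processing notes, cutadapt, Bowtie2 and SAMtools were used; their versions, their order, the genome build, the annotation and the treatment of reads that map to several transcripts are not given in the sources used here. Genes with near-identical copies, such as the CD8 chains, the metallothioneins, the lysozymes and the ribosomal proteins, are uncertain for that reason.

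The deposited files hold whole-number counts of reads per RefSeq accession, not normalized, with 1 file per library and no line for an accession without a count, which was taken as 0. In all 27306 accessions occurred. Of these, 133 were genomic (NT and NG) records, which held 0.71 to 1.92% of a library's counts, name no transcript and were left out. RefSeq's gene table of the assembly ARS-UCD2.0 was used for names only: 18973 of 27173 transcript accessions matched a gene symbol when versions were ignored (10155 with the same version), and these held 95.1% of the counts. Counts of accessions of 1 gene were summed, giving 12429 genes, 4066 of them from more than 1 accession. The 8200 unmatched transcripts held 3.6% of the counts and were kept as features of their own, for 20629 features in all. No coordinates are given, because the build behind the counts is not named.

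The 16 libraries held 8111862 to 14348753 counts, so that 3 counts correspond to between 0.212 and 0.375 CPM. PCR reads carry no molecular identifiers, and such limits cover counting error only. No pair of libraries was a duplicate: the highest correlation of log2 CPM was 0.95, and the lowest chi-square per gene between any 2 libraries was 75.8.

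Treatment was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, glmQLFit with robust estimation) with TMM scaling, edgeR's filter on low counts by group and no covariate. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the test's F value. The scaling factors lay between 0.61 and 1.14. Log2 CPM values use a prior count of 1. Before the data were examined, 35 gene lists (13 of cell type markers and 22 of pathways, 774 symbols, of which 650 occurred in the files) were written down, together with the tests, the alternatives and the rule for the genes to be named. Lists with at least 5 measured members, 31 in all, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, then with an estimated correlation and with fry. The list of mitochondrially encoded genes had 0 measured members, the erythroid and platelet lists had 1 each and the oocyte list had 2. Marker scores are the mean log2 CPM over the measured genes of a list, compared by a two-sided exact permutation test over all 11440 splits of the 16 libraries, or 126 splits of 9 and 35 splits of 7.

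The naming rule took genes past the threshold by size of change, filled up to 20 with the lowest p among genes with a symbol and a mean log2 CPM of at least 1. To these it added from each list the 2 members with the lowest p and the most abundant member, and 14 genes fixed by name. Of the 20 genes with the lowest p, 1 is not reported here. Values are also given for CSF1R, LDHA, TPI1, CEBPB, JUNB and EGR1, and for NEFL, HSD17B1 and SCARB1, which were chosen after their values were seen.

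Alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling or library size alone, no filter or at least 10 counts in every library, DESeq2 1.42.0, limma-voom with and without sample weights, edgeR without robust estimation, the replicate number as a block, 1 surrogate variable (sva 3.50.0), the leukocyte or the luteinising hormone surge score as a covariate, thresholds of 0.1 or a 2-fold change, and each library left out in turn. Chosen after the data were seen were the fits without the 7 leukocyte-rich libraries, with those 7 alone and with the kind of library as a covariate, counts per accession, the removal of unmatched transcripts, the other scalings for the gene lists, the 9 libraries with each left out, and the tests of the glycolysis score. A library was called leukocyte-rich where the mean over the pan-leukocyte markers exceeded that over the granulosa markers.

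The test was tried on counts simulated for each gene independently, with 1 mean per gene over all libraries, the real library sizes and the fitted spread. Changes were planted in genes with a mean log2 CPM of at least 1. The simulation held no difference between leukocyte-rich and other libraries, so the shares recovered need not hold for the real 16 libraries. Over 16 libraries and 9653 genes, it recovered 6% of genes changed 2-fold, 44.8% of those changed 4-fold and 69.7% of those changed 8-fold. Over the 9 granulosa-rich libraries and 9272 genes, the shares were 1.5%, 20.9% and 40.9%. A list of 20 genes changed 1.5-fold had an unadjusted p of 2.48e-05 over 16 libraries and 0.000323 over the 9, and an unchanged list 0.824 and 0.927; the simulated genes were independent of each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.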

Results

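RNA sequencing was carried out on 16 bovine libraries, 9 with the label control and 7 with the label treatment. Per the labels' protocols, each library held poly(A) RNA of granulosa cells, the somatic cells that surround the oocyte and make oestradiol in the ovarian follicle. The cells were aspirated through the vagina from the dominant follicle of Holstein cows at 63 ± 3 days after calving, within a cohort of 45 cows. The series title asks whether the granulosa transcriptome differs after a uterine disease has resolved. The labels do not say what the word treatment stands for, and the tissue field of all 16 libraries reads blood, so the groups are named here only as control and treatment. The files held 8111862 to 14348753 counts per library, with 11729463 ± 2005545 (SD, n = 9) in control and 10828953 ± 1555229 (SD, n = 7) in treatment. No 2 libraries agreed within sampling noise, and each was counted as 1 replicate. The labels do not tie single libraries to single cows, so p-values measure the spread between these libraries.

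The first question was which cells the libraries held. In 9 libraries the granulosa markers were far above the leukocyte markers. There CYP19A1 (aromatase, NM_174305.1), which converts androgen to oestradiol, lay between 281 and 29400 CPM (counts scaled to the total of the library after adjustment by the trimmed mean of M-values), with a median of 24500. INHA, the alpha subunit of the hormone inhibin, lay between 1590 and 3610 CPM, and FSHR, the receptor of follicle-stimulating hormone, between 112 and 622 CPM. In the other 7 libraries these genes were low and monocyte and macrophage genes were high. CYP19A1 lay between 0.987 and 902 CPM there, INHA between 0.381 and 97.8 CPM and FSHR between 0.0837 and 14.8 CPM. CD14, a receptor for bacterial lipopolysaccharide on monocytes and macrophages, lay between 1630 and 3840 CPM in those 7, against 5.47 to 300 CPM in the other 9. CSF1R, the receptor that macrophages need for survival, lay between 1200 and 2930 CPM against 3.67 to 129 CPM. PTPRC (CD45), present on all leukocytes, lay between 112 and 309 CPM against 6.53 to 88.6 CPM. HBB, the beta chain of haemoglobin, was at most 41.4 CPM in any library.

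The 9 libraries, called granulosa-rich below, were control replicates 2, 3, 4, 7 and 8 and treatment replicates 4, 5, 6 and 7. The 7 libraries, called leukocyte-rich below, were control replicates 1, 5, 6 and 9 and treatment replicates 1, 2 and 3. In the 7, the mean log2 CPM over 10 pan-leukocyte markers exceeded the mean over 18 granulosa markers. Thus 5 of 9 control and 4 of 7 treatment libraries were granulosa-rich (Fisher's exact test, two-sided, p = 1). The names describe the libraries and are not groups of the study. The largest principal component of the 1000 most variable genes held 65.2% of the variance and separated the 2 kinds of library, not the groups (two-sided exact permutation test, p = 0.766).

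**Figure D1:**
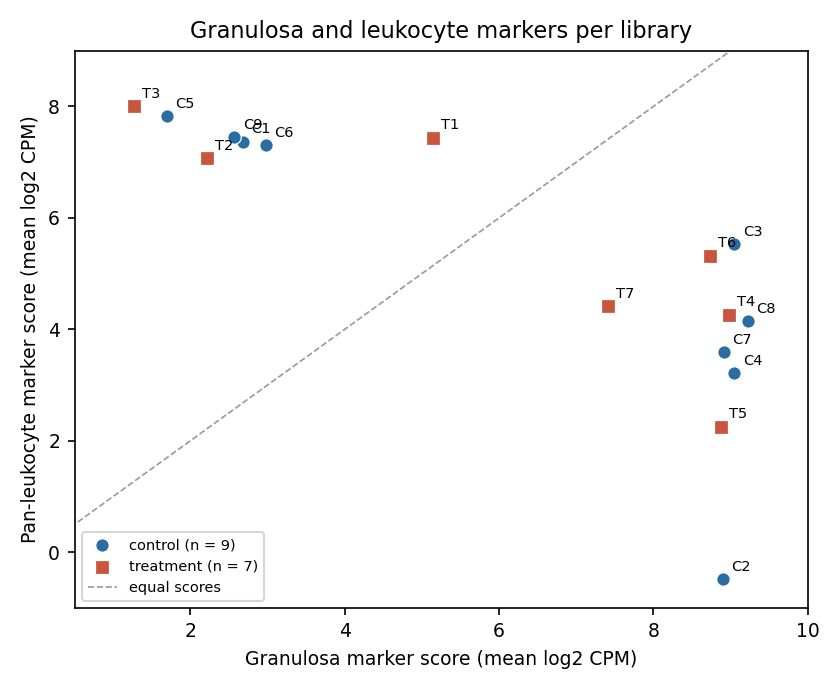
Mean log2 CPM of the granulosa markers (x axis) against that of the pan-leukocyte markers (y axis) in each of the 16 libraries; C is control, T is treatment and the number is the replicate. The 7 libraries above the dashed line of equal scores come from both groups, and treatment replicate 1 lies between them and the other 9 with a granulosa score of 5.14.

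**Figure D2:**
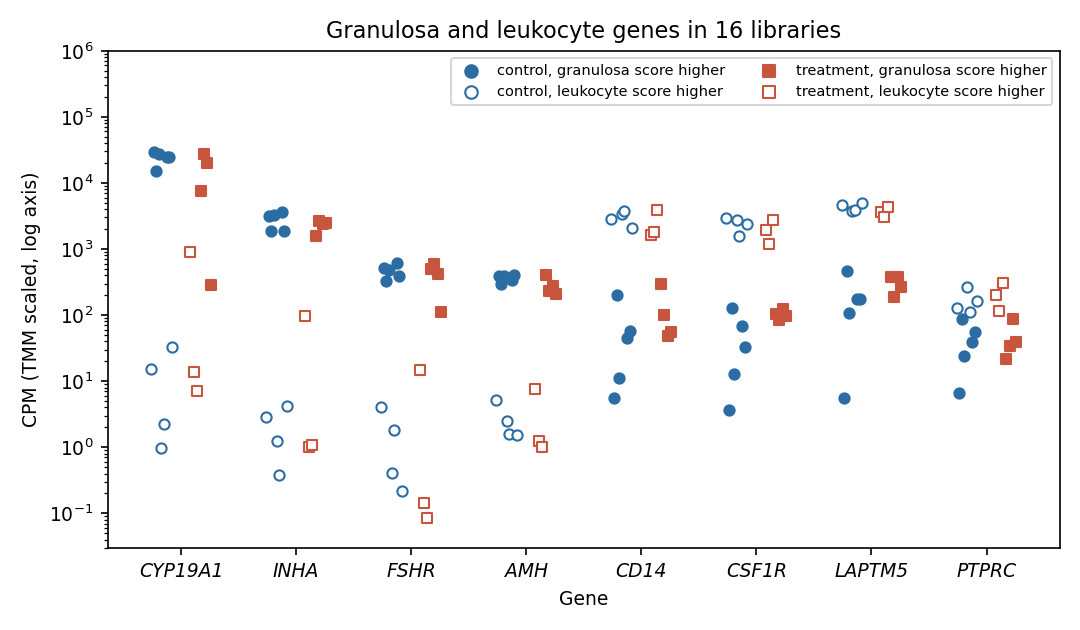
CPM (log axis) of 4 granulosa genes and 4 leukocyte genes in the 16 libraries, 1 point per library; blue circles are control, red squares treatment, and open symbols the libraries with the higher leukocyte score. CYP19A1 and CD14 part the open from the filled symbols by more than they part the groups, except that CYP19A1 in treatment replicate 7 (281 CPM) lies below treatment replicate 1 (902 CPM).

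Treatment and control were then compared for their cell type markers. The granulosa marker score was 6.12 ± 3.47 log2 CPM (SD, n = 9) in control and 6.09 ± 3.27 (SD, n = 7) in treatment. The pan-leukocyte score was 5.1 ± 2.77 (SD, n = 9) in control and 5.54 ± 2.07 (SD, n = 7) in treatment. Monocyte and macrophage markers were at 4.78 ± 2.96 (SD, n = 9) and 5.67 ± 2.02 (SD, n = 7), and T and NK cell markers at 2.89 ± 2.26 (SD, n = 9) and 3.74 ± 2.4 (SD, n = 7). The erythroid list was represented by HBB alone and lay 3.51 log2 units lower in treatment, with an unadjusted p of 0.0567 in the two-sided exact permutation test over 11440 splits. None of the 13 cell type lists differed between the groups by more than the spread between replicates (lowest adjusted p = 0.737, two-sided exact permutation test).

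The main comparison asked which genes differed between treatment and control over all 16 libraries. The genes that define a large oestrogen-active follicle varied widely within both groups. CYP19A1 was at 9.21 ± 6.46 log2 CPM (SD, n = 9) in control and 9.5 ± 4.84 (SD, n = 7) in treatment, with a fitted log2 fold change of -0.75 ± 1.74 (SE). INHA, INHBA (the activin beta A subunit), AMH (anti-Müllerian hormone) and FSHR had fitted log2 fold changes of -0.22 ± 1.6, -0.66 ± 1.6, -0.32 ± 1.3 and -0.17 ± 1.51 (SE). CYP11A1, which makes pregnenolone from cholesterol, was at -0.54 ± 1.32 (SE), and HSD3B1, the next enzyme towards progesterone, at -0.45 ± 1.31 (SE). STAR, which carries cholesterol into mitochondria, was at -1.29 ± 0.73 (SE), LHCGR, the luteinising hormone receptor, at -1.57 ± 1.66 (SE), and CYP17A1, the androgen-making enzyme of theca cells, at -1.14 ± 1.65 (SE). PTPRC was at 0.23 ± 0.66 (SE) and HBB at -1.94 ± 1.68 (SE). PTGS2 and PGR, also chosen beforehand, were not analysed here.

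No gene of the 9653 tested passed an adjusted p of 0.05 with edgeR's quasi-likelihood test. An unadjusted p under 0.05 was found for 163, where evenly spread p-values would give 483. Other splits of the 16 libraries into groups of the same sizes, not matched for the kind of library, gave a median of 262. limma-voom also called 0 genes. DESeq2 called 3, namely NEFL and 2 transcripts without a symbol, all left out of the main test for their low counts. The 20 genes with the lowest p, none of which passed, had unadjusted p from 0.00306 to 0.0144 and an adjusted p of 0.9999. Among those with lower values in treatment were CRYM, a thyroid hormone binding protein, at -2.05 ± 0.6 (SE), GOT1, a cytosolic aspartate aminotransferase, at -2.68 ± 0.84, and the orphan nuclear receptor NR4A1 at -3.79 ± 1.29. PDLIM3 was at -2.18 ± 0.71, DRC1 at -3.75 ± 1.28, the small heat shock protein HSPB8 at -3.35 ± 1.19, VPS39 at -1.46 ± 0.49, the glucocorticoid-induced TSC22D3 at -1.17 ± 0.42 and FAM114A2 at -0.99 ± 0.3. Among those with higher values were the metallothionein MT2A at 2.8 ± 0.97, the angiotensin receptor AGTR1 at 3.48 ± 1.25, GPRC5B at 2.64 ± 0.9 and ECRG4 at 3.42 ± 1.21. CBLN3 was at 3.25 ± 1.13, MAT1A at 1.95 ± 0.71, SMG8 at 1.15 ± 0.38 and JMJD6 at 0.69 ± 0.24. SELP, an adhesion molecule of platelets and endothelium, and LYZ2, a lysozyme, were at 5.53 ± 1.59 and 4.31 ± 1.46, and for both a single library, treatment replicate 3, lay far above the other treatment libraries (0.13 and -0.99 without it). In other genes, too, 1 library carried much of the value. Without treatment replicate 7, MT2A was at 0.06, AGTR1 at 0.19, GPRC5B at 0.83 and CBLN3 at 0.71. Without control replicate 8, DRC1 was at -0.95 and HSPB8 at -2.1, and without treatment replicate 5 SMG8 was at 0.69.

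Of 31 groups of genes tested, 5 stood apart from the remaining genes under a preset correlation and 0 with an estimated correlation between genes (adjusted p = 0.992 for each of the 5), and no member passed over all genes or adjusted over the list alone. Of 18 measured glycolysis genes, 17 had lower and 1 had higher fitted values in treatment, with a median log2 fold change of -0.38 (camera, adjusted p = 5.1e-08, and unadjusted p = 0.0651 with an estimated correlation). ENO1 (enolase) was at -0.65 ± 0.25 (SE), PDK1, which restrains pyruvate entry into the citric acid cycle, at -0.7 ± 0.36 and GAPDH at -0.42 ± 0.33. Of 13 T and NK cell markers, 11 had higher fitted values (median 0.83, adjusted p = 0.00378), among them CD8B at 1.36 ± 0.93 and CD8A at 1.15 ± 0.97, the chains of the cytotoxic T cell coreceptor (0.58 and 0.63 without treatment replicate 1). Of 26 interferon-stimulated genes, 21 had higher fitted values (median 0.48, adjusted p = 0.00705), among them the antiviral genes RSAD2 at 1.31 ± 0.81 and IFITM1 at 0.68 ± 0.42 (0.43 and 0.37 without treatment replicate 1). Of 24 immediate early and heat shock genes, 13 had lower fitted values (median -0.05, adjusted p = 0.00705), among them JUND at -1.08 ± 0.45. In the 7 leukocyte-rich libraries alone this list went up (19 of 24 members, median 0.51, adjusted p = 0.0159, and 0.894 with an estimated correlation). With library size alone the median of that list was 0.04, while its test kept the direction down. Of 28 cell cycle genes, 20 had higher fitted values (median 0.22, adjusted p = 0.0393), among them NUSAP1 at 1.1 ± 0.61 and CCNB1 at 0.47 ± 0.37.

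With an estimated correlation the unadjusted p was 0.264 for T and NK cell markers, 0.352 for interferon-stimulated genes, 0.221 for immediate early and heat shock genes and 0.431 for cell cycle genes. The preset call of glycolysis held without each of the 16 libraries (highest adjusted p = 0.000916), and the other 4 ended without some. That of T and NK cell markers ended without control replicate 2 or treatment replicate 1 or 3 (adjusted p from 0.16 to 0.297). That of interferon-stimulated genes ended without control replicate 2 or 4 or treatment replicate 1 or 3 (0.0605 to 0.914). That of immediate early and heat shock genes ended without control replicate 7 or treatment replicate 4, 5 or 6 (0.0636 to 0.458), and that of cell cycle genes without control replicate 3, 4, 7 or 8 or treatment replicate 1, 2, 3 or 4 (0.0876 to 0.787) and with library size alone as the scaling (0.0798). The other 26 lists did not pass (adjusted p from 0.0735 to 0.988 with the preset correlation). They included steroidogenesis (median -0.48, adjusted p = 0.0881, and 0.0391 with library size alone as the scaling), luteinisation (median -0.5, adjusted p = 0.15), inflammatory cytokines and chemokines (median 0.67, adjusted p = 0.15) and Toll-like receptor and NF-kB signalling (median 0.07, adjusted p = 0.504). Single genes of these groups with low unadjusted p were ANGPT2, an antagonist of vessel stability, at 2.27 ± 0.89 (SE), AREG, a growth factor induced by luteinising hormone, at 2.55 ± 1.2, and the immunoglobulin joining chain JCHAIN at -3.18 ± 1.3, and none passed the test. Each rested largely on 1 library. ANGPT2 was at 0.85 without treatment replicate 4. AREG was at -1.16 without treatment replicate 7 (956 CPM, other treatment libraries 0.89 to 29.1), and its mean log2 CPM was 4.08 in control and 3.61 in treatment. JCHAIN was at -0.79 without control replicate 3 (2190 CPM, other control libraries at most 212).

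The same comparison was repeated without the 7 leukocyte-rich libraries, a choice made after the data were seen, leaving 5 control and 4 treatment libraries. Glycolysis genes had lower values in these 4 treatment libraries than in the 5 control libraries. The mean log2 CPM of the 18 measured genes was 7.21 ± 0.23 (SD, n = 5) in control and 6.23 ± 0.27 (SD, n = 4) in treatment, and every treatment library lay below every control library. The difference of -0.98 had a two-sided exact permutation p of 0.00794, the smallest that 126 splits can give, and an adjusted p of 0.111 over 21 pathway lists. With so few splits, a single list at the smallest p could not have passed over the 21 lists. Of the 18 genes 16 had lower fitted values and 7 passed adjusted over the list alone, while none passed over all genes. LDHA, which reduces pyruvate to lactate, was at -1.59 ± 0.35 (SE), PDK1 at -1.41 ± 0.35, ENO1 at -1.06 ± 0.32, GAPDH at -0.87 ± 0.21 and the triosephosphate isomerase TPI1 at -0.82 ± 0.2. LDHA and TPI1 were chosen for naming after their values were seen.

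**Figure D3:**
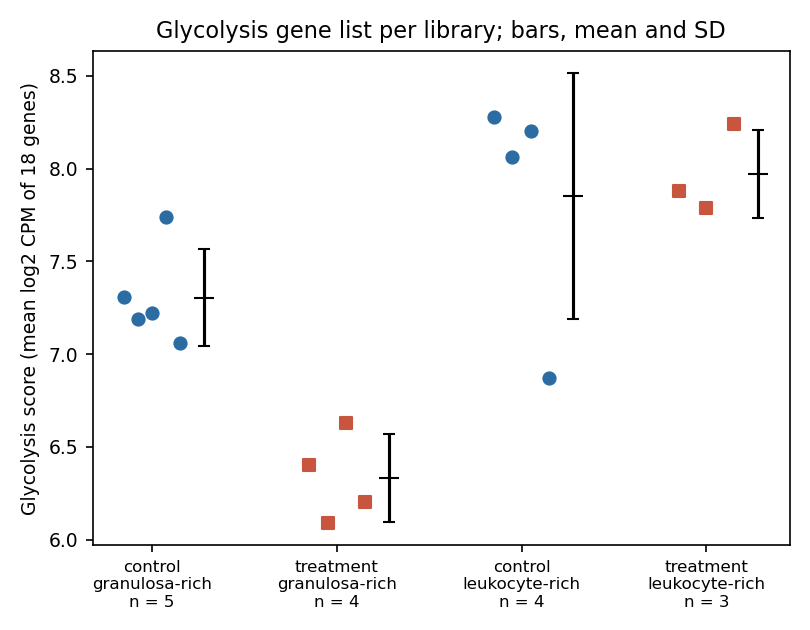
Mean log2 CPM of 18 glycolysis genes (y axis), with all 16 libraries scaled together, by group and kind of library; points are libraries, and the bars give the mean and SD. Among the granulosa-rich libraries the control values lie between 7.06 and 7.74 and the treatment values between 6.09 and 6.63, and among the leukocyte-rich libraries the groups overlap.

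Glycolysis was the only list of the 29 tested in these 9 libraries that passed with an estimated correlation (camera, median log2 fold change -0.82, adjusted p = 0.0286), and 10 lists passed with the preset one. With fry 1 list passed in these libraries, and which one is not given here. Immediate early and heat shock genes had 20 of 24 members with lower fitted values (median -0.62, adjusted p = 1.05e-05, and adjusted p = 0.471 with an estimated correlation). Of these, 4 passed adjusted over the list alone and 0 over all genes, with NR4A1 at -5.51 ± 1.22 (SE), JUNB at -3.12 ± 0.69, JUND at -1.7 ± 0.41 and EGR1 at -2.55 ± 0.75. The mean log2 CPM of the immediate early list was 6.13 ± 0.9 (SD, n = 5) in control and 4.94 ± 0.89 (SD, n = 4) in treatment. Its exact permutation p was 0.0952, with an adjusted p of 0.388. Monocyte and macrophage markers had 11 of 12 members with higher fitted values (median 1.05, adjusted p = 1.17e-06, and adjusted p = 0.471 with an estimated correlation). Their score was 3.62 ± 1.8 (SD, n = 5) in control and 5.19 ± 0.73 (SD, n = 4) in treatment, with an exact permutation p of 0.135 and an adjusted p of 0.515. Steroidogenesis genes had 12 of 16 members with lower fitted values (median -0.55, adjusted p = 0.00584, and adjusted p = 0.274 with an estimated correlation). The mean log2 CPM of the steroidogenesis list was 7.82 ± 0.44 (SD, n = 5) in control and 6.91 ± 0.29 (SD, n = 4) in treatment, with an exact permutation p of 0.0159 and an adjusted p of 0.111. That of the luteinisation list was 6.11 ± 0.38 (SD, n = 5) and 5.37 ± 0.26 (SD, n = 4), with the same 2 p-values. Both lists hold STAR, HSD3B1, CYP11A1 and SCARB1, so these results are not independent. The other 6 lists past the threshold with the preset correlation had an adjusted p from 0.339 to 0.674 with an estimated one, and each call ended without some libraries. They were cell cycle (up, adjusted p = 0.0033, ended without control replicate 7 or treatment replicate 4), interferon-stimulated genes (up, 0.0069, without control replicate 2 or treatment replicate 4), the luteinising hormone (LH) surge and cumulus expansion (down, 0.0136, without control replicate 4 or 7 or treatment replicate 4 or 6), granulosa markers (down, 0.0218, without control replicate 2 or treatment replicate 7), gonadotropin and growth factor receptors (down, 0.0234, without control replicate 7 or treatment replicate 5 or 7) and luteinisation (down, 0.0376, without control replicate 7 or treatment replicate 4). Without these libraries the adjusted p of the 6 lay between 0.0505 and 0.557. The LH surge list had a median of 0.49 and a mean of -0.57, so its test followed the mean. Of its members and of those of luteinisation, 2 each passed adjusted over the list alone and 0 over all genes. Granulosa markers were at 8.94 ± 0.16 (SD, n = 5) and 8.39 ± 0.74 (SD, n = 4), with an exact permutation p of 0.0397 and an adjusted p of 0.361. Treatment replicate 7 carried most of that difference of -0.54, which was -0.17 without it (exact permutation p = 0.143). The 5 measured theca markers were at 4.11 ± 0.54 (SD, n = 5) and 2.8 ± 1.23 (SD, n = 4), a difference of -1.31 with an exact permutation p of 0.0556 and an adjusted p of 0.361. It was -1.76 without treatment replicate 7 (unadjusted p = 0.0179) and -0.76 without treatment replicate 4 (unadjusted p = 0.143). Of the 9272 genes tested edgeR called 0, and 433 had an unadjusted p under 0.05, where evenly spread p-values would give 464. Other splits of the 9 libraries into groups of the same sizes gave a median of 307. CEBPB, a transcription factor induced by luteinising hormone, had the lowest unadjusted p (0.000135) at -2.23 ± 0.38 (SE), and it did not pass. The glycolysis call with an estimated correlation ended when any 1 of 8 libraries was left out, with adjusted p from 0.0522 to 0.147, and held without control replicate 8 (adjusted p = 0.0437). It also ended with library size alone as the scaling (adjusted p = 0.0731).

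Among the 7 leukocyte-rich libraries (4 control and 3 treatment) the glycolysis score was 7.97 ± 0.66 (SD, n = 4) in control and 8.1 ± 0.22 (SD, n = 3) in treatment, a difference of 0.13 with an exact permutation p of 0.943. The sign rested on control replicate 9. With all 16 libraries scaled together its score was 6.87, against 8.06 to 8.28 in the other leukocyte-rich controls and a treatment mean of 7.97. The smallest p that 35 splits allow is 0.0286. Of 30 lists tested in these 7 libraries, 7 passed with the preset correlation and 0 with an estimated one. Inflammatory cytokines and chemokines were at 5.37 ± 0.47 (SD, n = 4) and 6.3 ± 0.7 (SD, n = 3), with an exact permutation p of 0.114 (camera, adjusted p = 4.9e-05 with the preset correlation and 0.492 with an estimated one). T and NK cell markers were at 3.68 ± 1.17 (SD, n = 4) and 4.8 ± 0.66 (SD, n = 3), with an exact permutation p of 0.171 (camera, adjusted p = 1.68e-05 and 0.894). Of the 9912 genes tested edgeR called 0, and 259 had an unadjusted p under 0.05, where evenly spread p-values would give 496. With the kind of library as a covariate over all 16 libraries edgeR called 0 genes, and 242 had an unadjusted p under 0.05.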

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

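The test of each group for a library far from the others (Dixon's test at the 95% level) was fixed beforehand, while the tests of dilution and of a response to luteinising hormone in treatment replicate 7 were chosen after its values were seen. Over 178 groups of values it set apart 15, where about 8.9 would be set apart if the values of each group were normally spread. The 15 count HBB in treatment replicate 6 both as a gene and as the erythroid score.

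In treatment replicate 7 the score of the genes of the luteinising hormone (LH) surge and of cumulus expansion was 6.83 log2 CPM, against 2.53 to 3.8 in the other 6 treatment libraries. MT2A (12.69 log2 CPM, others 6.22 to 8.61) and AGTR1 (6.41, others -1.96 to 1.42) were also set apart there. Against the median of the other 8 granulosa-rich libraries, CYP19A1 was at a ratio of 0.0114, HSD17B1 at 0.0423 and FSHR at 0.232. INHBA was at 0.206 (10400 CPM, other 8 from 34400 to 109000) and LHCGR at 0.181 (9.36 CPM, other 8 from 0.595 to 98.5). TNFAIP6, a hyaluronan-binding protein of the expanding cumulus, was at 44.5, AREG at 140 and the lipoprotein receptor SCARB1 at 25.4. STAR, which luteinisation would raise, was at 0.127 (11.6 CPM, other 8 from 17.3 to 375). Dilution of granulosa cells by other cells would lower INHA along with CYP19A1, and INHA was at 0.972 of that median, which argues against it. The LH score of 6.83 was the highest of the 9 granulosa-rich libraries (other 8 from 3.01 to 6.11), but that score is also what drew attention to the library, and the low STAR goes the other way. The score covers 13 measured genes of the 25 listed, and PTGS2 and PGR were not among them. Whether the follicle had already met the LH surge is left open, as are an exchanged sample and a difference between the groups, which a single library cannot show.

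Treatment replicate 5 was set apart by NR4A1 (-3.48 log2 CPM, the value of a count of 0, others 0.6 to 3.44), HSPB8 (-3.48, others -0.55 to 1.03), VPS39 (4.81, others 6.32 to 7.04) and a ribosomal protein score of 9.48 (others 8.17 to 8.74). Treatment replicate 3 was set apart by SELP (8.46, others -2.21 to 1.05) and LYZ2 (8.96, others -0.55 to 2.05). HBB, the single measured gene of the erythroid list, was at 4.62 in treatment replicate 6 (others -3.48 to -0.98). In control, replicate 2 had low IFITM1 (1.09, others 2.97 to 4.63) and a low oocyte marker score over 2 genes (-1.5, others 0.18 to 1.52), replicate 9 had low PDK1 (6.24, others 8.1 to 9.39) and replicate 3 had low JMJD6 (2.44, others 2.93 to 3.4).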

How the results depend on the processing

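The fits without or with only the leukocyte-rich libraries, with library kind, and with other scalings for lists were added after the data were seen. The count of genes past the threshold was 0 in every edgeR and limma fit run, with 46 to 1180 genes at an unadjusted p under 0.05, and DESeq2 called 3 (the cause was not tested). Of 1714 alternative values of 53 named genes, 1615 kept their direction and 99 changed sign without passing. The count of gene lists, 5 with the preset correlation, was 0 with an estimated correlation and 0 with fry, 10 without the 7 leukocyte-rich libraries, 9 with library kind as a covariate, 7 in the 7 leukocyte-rich libraries alone, and 5 to 6 under the other 3 scalings (causes not tested). With library size alone the cell cycle call ended (adjusted p = 0.0798) and steroidogenesis passed (down, 0.0391), and with upper-quartile scaling monocyte and macrophage markers passed (up, 0.0446). Leaving out 1 library gave 2 to 13 lists: 2 without treatment replicate 1 or 3, 3 without control replicate 4 or 7, 8 without control replicate 1, 9 without control replicate 5 or 6, 10 without control replicate 9 or treatment replicate 6 or 7, and 13 without treatment replicate 5. In the 7 leukocyte-rich libraries alone, 12 of 30 lists had another direction than over 16, 3 of them past the threshold in either fit: acute phase and complement (up, adjusted p = 0.00769), immediate early and heat shock genes (up, 0.0159) and cell cycle (down, 0.0969). With an estimated correlation none of the 3 passed (0.492, 0.894 and 0.933); the cause was not tested. Cell type scores passed in none of the alternatives run, with 218 of 253 differences keeping their direction. The first principal component held 50.1% of the variance over all genes. Whether replicate numbers pair the libraries could not be told. Deviations of libraries with one number correlated between -0.6 and 0.6, and no library matched its own number best. The correlations followed the kind of library, which was not removed. They were positive only for numbers 1, 4 and 7, where both libraries were of the same kind. The replicate block over numbers 1 to 7 gave 0 genes (46 at an unadjusted p under 0.05) and 6 lists. The planned pseudocount for normalized values was not run, since the files hold counts. Simulated 2-fold changes were mostly missed at these depths and spreads (6% recovered over 16 libraries), and smaller changes of single genes were not simulated.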

Other observations

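The tests of blood cells, of the groups and of the labels for the leukocyte-rich libraries, all tests of the glycolysis score and the split test of lists with an estimated correlation were chosen after the data were seen (the bound for the scaling test was set before its value was known), while the other split tests were set before their results.

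NEFL, a neurofilament subunit best known from neurons, was among the 3 features that DESeq2 called. It had 0 to 9 counts in the 9 control libraries (median 3) and 7 to 93 counts in the 7 treatment libraries (median 44), in both kinds of library. That is 0.339 ± 0.309 CPM (SD, n = 9) against 3.96 ± 3.38 CPM (SD, n = 7). Without the filter on low counts edgeR gave a log2 fold change of 3.53 ± 0.76 (SE), an unadjusted p of 0.000173 and an adjusted p of 0.8. The two-sided exact permutation p was 0.00035, for a gene chosen because it was called. XR_001495519.1, a non-coding transcript without a symbol, had 0 counts in 8 of 9 control libraries and at most 2 in the other, and 1 to 15 counts in all 7 treatment libraries. Its exact permutation p was 0.000175, likewise for a feature chosen because it was called. The third feature, XM_015471806.1, had a median of 6 counts in either group (exact permutation p = 0.258). Its counts reached 1655 in control and 154 in treatment, with 29 ± 51.5 CPM (SD, n = 9) against 2.27 ± 4.36 CPM (SD, n = 7).

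Beside glycolysis, single genes in the 9 granulosa-rich libraries had large fitted differences that did not pass. The monocyte chemoattractant CCL2 was at 3.28 ± 0.99 log2 units (SE, adjusted p = 0.983 with edgeR) and ANGPT2 at 3.34 ± 1.03 (1.41 without treatment replicate 4). Epithelial markers were present in part of these libraries: their score was 6.33 log2 CPM in control replicate 3, 5.2 in control replicate 8 and 5.18 in treatment replicate 7, against -1.53 in treatment replicate 4.

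In 7 of 16 libraries leukocyte markers exceeded granulosa markers. Unfractionated blood in the aspirate would bring neutrophil transcripts, but the summed CPM of 4 measured neutrophil genes (of S100A8, S100A9, S100A12, CXCR1 and CXCR2) was at most 0.205 of CD14 in these 7, and HBB was at most 30.6 CPM, which argues against it as the main source. The treatment group does not account for it either, since 4 of the 7 carry the control label. Mononuclear blood cells, macrophages of the follicle or a sample of another origin remain open: PF4, of platelets and some monocytes, lay between 24.4 and 1740 CPM. All 16 libraries carry identical labels apart from their titles, so an unlabelled difference in the sampled material (other cells aspirated, or a sample exchanged) cannot be told apart from these.

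Glycolysis genes had lower values in the treatment libraries among the 9 granulosa-rich ones, and the score difference did not pass over the 21 pathway lists (exact permutation test, adjusted p = 0.111). That adjusted test decides nothing, because with 126 splits a single list at the smallest p of 0.00794 could not have passed. A larger share of leukocytes would lower the list only if leukocyte-rich libraries held less of it. With all 16 scaled together its score was 7.9 ± 0.49 (SD, n = 7) in those and 6.87 ± 0.56 (SD, n = 9) in the granulosa-rich ones. This argues against leukocytes as the cause of lower values. The median log2 fold change was -0.82. With the pan-leukocyte score as a covariate it was -0.78 (camera with an estimated correlation, p = 0.00386), although the adjusted p then was 0.112. Scaling is argued against by a score difference of -0.8 with library size alone. Without each library in turn the score difference was -0.89 to -1.1. Groups that lie fully apart stay apart when 1 library is left out, so that test could hardly have come out otherwise. The list call with an estimated correlation did depend on single libraries. It held only without control replicate 8 (camera, adjusted p = 0.0437) and ended without any other (0.0522 to 0.147). Whether the kinds of library differ in this is left open: with all 16 scaled together the differences were -0.97 and 0.12, with an exact permutation p of 0.0313 over 4410 relabellings for a list picked by its value in the 9, and 0.488 when adjusted over the 21 pathway lists. The sign of the 0.12 rested on control replicate 9, with a score of 6.87 against 8.06 to 8.28 in the other leukocyte-rich controls. Chance could account for the call, as 5 of 100 splits of the 9 libraries, the real one included, gave 1 list with an estimated correlation (highest other 1). Which list passed in the other splits was not recorded. A lower glycolytic programme in treatment therefore stays a hypothesis.

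Other splits of the same libraries, 100 each with the real one, did not exclude chance for the counts of lists and of genes at an unadjusted p under 0.05. The counts of 0 genes cannot be tested this way, since all 100 splits give at least 0 (highest other 1274 over 16 libraries and 3 over the 9). Over 16 libraries, 80 gave at least 163 genes at an unadjusted p under 0.05 (highest other 3452) and 86 gave at least 5 lists with the preset correlation (highest other 21). The real split put 3 of the 7 leukocyte-rich libraries in treatment, while the other splits were not matched for library kind. These shares therefore do not compare the real split with splits of the same balance alone. The split with 1274 genes put 6 of the 7 leukocyte-rich libraries on one side, and so did 5 other splits, which called 0 genes each. These 6 splits had 843 to 3452 genes at an unadjusted p under 0.05, against a median of 260 in the remaining splits, which points to that structure of the samples for these counts but does not by itself set the number of calls. Over the 9 granulosa-rich libraries, 36 gave at least 433 genes at an unadjusted p under 0.05 (highest other 1093) and 47 gave at least 10 lists (highest other 18).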
